A study of Mus musculus with 4 samples.

How the data were processed

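Total RNA of mouse ventricular muscle was labelled with Cy5 after amino allyl amplification and hybridised to Toray oligonucleotide arrays, per the labels. There were 4 arrays in 2 groups of 2, wild type and Trpc6 knockout, and each array carried the RNA of 1 sample. The labels number the samples of a group and do not say whether they came from separate animals, so the p-values measure the spread between these samples, which may be technical.

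The deposited scanner files hold, for each of 27456 spots, the median pixel intensity of the spot and of its local background at 635 nm on a linear scale, per the file headers. The headers also give straight lines fitted between 3 scanner gains, and how the gains were joined is not given in the sources used here. The authors also deposited a table of processed values of the same arrays, as linear intensity. Setting each of its columns against the spot medians of its array showed a straight line on every array, with residuals of at most 0.0523 units, close to the rounding of the table. A constant of 78.4 to 87.7 units was subtracted per array, near the median of that array's blank spots, and the rest was scaled by 0.807 to 1.02 so that the median of each column was 25. Cells of 3714 to 4955 dim probes per array were empty. Scale, centring and direction of the authors' table were thereby known, and the rule by which they emptied cells was not.

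The arrays held 23473 gene probes, 384 blank spots, 96 negative control spots and 48 positive control spots. Gene symbols came from the platform annotation, which gave 20690 probes 1 symbol, no probe several and 2783 probes none. Probes without a symbol are unnamed here. Positions came from the GRCm38.p6 gene table and served only to find the genes near Trpc6.

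Spot medians were corrected with normexp in limma 3.58.1 under R 4.3.3, with an offset of 50, fitted on all spots. Local background was not subtracted, because it followed the spot signal on these arrays, with a correlation of log2 values across spots of 0.928 to 0.965. Control spots were then left out, spots of 1 probe were averaged, and log2 values were quantile normalized between arrays. A probe was above background on an array when its spot median exceeded the 95th percentile of that array's blank and negative control spots, and it was kept when this held on at least 2 arrays. Of 19117 kept probes, 16999 had a symbol, and these stood for 15955 genes. A gene with several kept probes was represented by its brightest. This concerned 977 genes, and in 53 of them the probes differed in sign while at least 1 of them had an unadjusted p under 0.05. The offset shrinks fold changes of dim probes, so that ratios in the authors' table are larger for these.

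The groups were compared with lmFit and eBayes in limma, without covariates, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. All p-values are two-sided, except that for the count of genes near Trpc6. The fit had 2 residual degrees of freedom and 2.49 prior degrees of freedom. Each fold change is the knockout minus the wild-type mean of log2 values and is given with its limma standard error. An exact permutation of 2 against 2 samples cannot give a p under 0.05, and single genes were tested with limma's moderated variance, which combines the spread of the gene with that shared across genes.

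The comparison, the alternatives, 35 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered cardiac pathways, cell types and technical signatures. Of their 1013 entries, 918 matched a named probe. Lists with at least 5 kept genes were tested with camera at a preset correlation between genes of 0.01, adjusted over the 33 lists tested, then with an estimated correlation and with fry, for a shared direction and, as its mixed test, for either. Several lists share genes and are not independent. The limma p-values of members were also adjusted within each list alone, without correction for the number of lists. Named were Trpc6, up to 12 genes per direction, up to 4 members of each list with the smallest p, and every kept TRPC channel. Genes past the threshold came first, and places left over went, in order of p, to genes without overlap of the groups and with an absolute log2 fold change of at least 0.58. Numbered gene models were left out of the names. Genes named outside this rule are said to have been chosen after their values were seen.

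Genes within 10 Mb of Trpc6 were set against the rest of the chromosome by 10000 circular shifts of gene positions. The alternatives changed the background correction, the normalization, the filter, the source of values (the authors' table, with a floor of 2.3), the choice of probe, the variance model, the set test and the window, added the replicate number as a term, or left out each array in turn.

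The limma and camera steps were tested on simulated arrays with the spread of the 15955 genes. Over 10 draws with 200 changed genes each, 82.6% of genes changed by 0.5 on the log2 scale were recovered, 98.8% of those changed by 1, and 100% of those changed by 3. These shares hold for 200 changed genes, since the adjustment is stricter when fewer genes change. In the real arrays Perp, with a log2 fold change of 0.85 and a limma p of 2.31e-05, had an adjusted p of 0.369. Of 205.2 genes called per draw, 14.7 were false. In 20 draws without any change, 0.05 genes and 0.1 lists were called per draw. With the real arrays regrouped so that each group held 1 wild-type and 1 knockout array, 3 and 4 lists were called. The simulated rate of list calls is therefore too low for these arrays. Plots were drawn with matplotlib 3.10.9.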

Results

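Gene expression was measured in ventricular muscle of male mice of the strain 129SV, in 2 wild-type samples and 2 samples with a genetic deletion of Trpc6, which encodes a calcium-permeable cation channel opened downstream of receptors. The comparison asks which transcripts differ in the ventricle without this channel. Each sample was read on 1 array in 1 colour. The median probe intensity was 95.5 and 106 units on the wild-type arrays and 97.7 and 97.1 units on the knockout arrays, against a blank spot median of 78.5 to 87.6 units, so that the typical probe lay close above background. Between 76.3% and 83.2% of the gene probes were above background, and the number of arrays limits the precision of every value. Values below are normalized log2 intensities, given as mean ± SD with n = 2 arrays per group, and fold changes are given ± standard error.

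Trpc6 itself could not be used to check the labels. Its single probe read 80.5 and 89.2 units on the wild-type arrays and 84.1 and 82.6 units on the knockout arrays, and was not above background on any of the 4 arrays, so no fold change is given. The authors' table lists 1 value for it, 2.1 units on the first wild-type array. Of the other TRPC channels, 4 were kept. Trpc5, Trpc4, Trpc1 and Trpc7 had log2 fold changes of -0.07 ± 0.04, 0.02 ± 0.04, -0.01 ± 0.04 and 0.01 ± 0.04, and none had an unadjusted p under 0.05. Trpc4 was above background on 1 of 2 wild-type arrays. Trpc5, Trpc4 and Trpc7 were dim, and the offset shrinks fold changes of dim probes, so these values do not show that the channels were unchanged. In the authors' table Trpc5 averaged 8.1 units in wild type and 5 units in the knockout, a knockout to wild-type ratio of 0.62. The same ratio was 1.04 for Trpc7 and 0.97 for Trpc1, and Trpc4 had none.

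Across all genes tested, the median absolute log2 fold change between wild-type and knockout ventricle was 0.043. It was 0.039 and 0.040 with the arrays regrouped so that each group held 1 array of each genotype. The offset also shrinks fold changes of dim probes, so this median does not measure the size of the genotype differences. Among the genes named by the rule, those higher in the knockout included Perp, a tetraspan membrane protein of desmosomes and a p53 target, the alpha-tubulins Tuba8 and Tuba4a, the transcriptional repressor Nfil3, and Acta1 and Nppa, genes of skeletal alpha-actin and atrial natriuretic peptide. Ly6g, a neutrophil surface protein, and Ccn2, connective tissue growth factor, were lower. None of these genes passed the test over all genes, and Ccn2 had an unadjusted limma p of 0.108. As groups, genes of fatty acid uptake and oxidation and immediate early genes lay lower in the knockout, and ribosomal protein, cell cycle and glucocorticoid target genes lay higher, each by camera with a preset correlation. None of these 5 calls held with an estimated correlation, where adjusted p = 0.88 for each, or with fry's test of a shared direction. Camera with an estimated correlation called 0 lists in each of the 3 splits of the arrays into pairs. The ribosomal list's estimated correlation was 0.0098, near the preset 0.01, yet its unadjusted camera p went from 2.39e-04 to 0.0663. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit, and could hardly call a list here. A call lost with this setting therefore does not by itself show correlation between genes, nor that a list was unshifted.

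Of 15955 genes tested with limma, 0 had an adjusted p under 0.05 and 0 had one under 0.10, and the smallest was 0.369. At an unadjusted p under 0.05 there were 585 genes higher and 491 lower in the knockout, 1076 together, where chance gives 797.75. The split was 397 higher and 676 lower after scaling to a common median, 511 and 539 with a normexp offset of 16, and 217 and 462 in the authors' table, which also differs in background and floor. The groups did not overlap in 36.8% of genes, against 33.3% by chance. Hba-a2 alone combined no overlap with a difference of at least 2-fold.

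Perp was at 9.04 ± 0.04 in wild type and 9.90 ± 0.05 in the knockout, 1.81-fold higher, with an unadjusted p of 2.31e-05. Its authors' values averaged 435 and 865 units. Tuba8 was at 9.39 ± 0.10 and 10.08 ± 0.01, Nfil3 at 6.80 ± 0.11 and 7.43 ± 0.08, and Ankrd9 at 7.84 ± 0.09 and 8.50 ± 0.14, or 1.61-fold, 1.55-fold and 1.58-fold higher. Gadd45g, a growth arrest and stress gene, was at 7.21 ± 0.41 and 8.06 ± 0.27, and Tuba4a at 12.24 ± 0.37 and 12.86 ± 0.19. Acta1 was at 11.10 ± 0.24 and 11.82 ± 0.39, and Nppa at 11.66 ± 0.03 and 12.30 ± 0.43. These genes, like all 16 shown in the figure, had not passed and were filled in by the naming rule, which then admits only genes without overlap of the groups. Of the 16, Hbb-bt, Hbb-b2, Wdr49 and Ccn2 had unadjusted limma p-values of 0.0708, 0.0848, 0.0932 and 0.108.

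Single arrays weighed on many of these differences. Without the array that mattered most, the log2 fold change of Perp was 0.82 in place of 0.85, of Nppa 0.33 in place of 0.64, of Tuba4a 0.36 in place of 0.62, of Acta1 0.44 in place of 0.71, of Gadd45g 0.56 in place of 0.85, of Asb11 -0.44 in place of -0.73, and of Ddit4 0.45 in place of 0.96. B2m, the light chain of MHC class I, was at 9.63 and 9.61 on the wild-type arrays and at 10.08 and 11.07 on the knockout arrays. Ddit4, an inhibitor of mTOR signalling, was at 6.85 and 7.86 in wild type and 8.26 and 8.36 in the knockout. The beta-globin genes Hbb-bt and Hbb-b2 were at 7.01 and 7.24 on the first wild-type array and between 8.19 and 8.83 on the other 3. Among the lower genes, Ly6g was at 7.90 ± 0.13 in wild type and 7.15 ± 0.29 in the knockout, 1.69-fold lower, and Asb11, which encodes an ankyrin repeat and SOCS box protein, was at 10.50 ± 0.42 and 9.77 ± 0.29. Wdr49 was at 7.55 and 8.32 on the wild-type arrays and at 7.53 and 7.05 in the knockout, and its log2 fold change of -0.64 was -0.26 without the second wild-type array. Ccn2 was at 8.22 and 9.53 on the wild-type arrays and at 7.92 and 8.06 in the knockout. Its log2 fold change of -0.89 was -0.23 without the second wild-type array. The sign of Tuba4a, Asb11 and Ccn2 turned when the local background was subtracted. Fold changes spread widely with that setting, with an SD of 0.91 in place of 0.19 over genes of fatty acid uptake and oxidation.

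**Figure D1:**
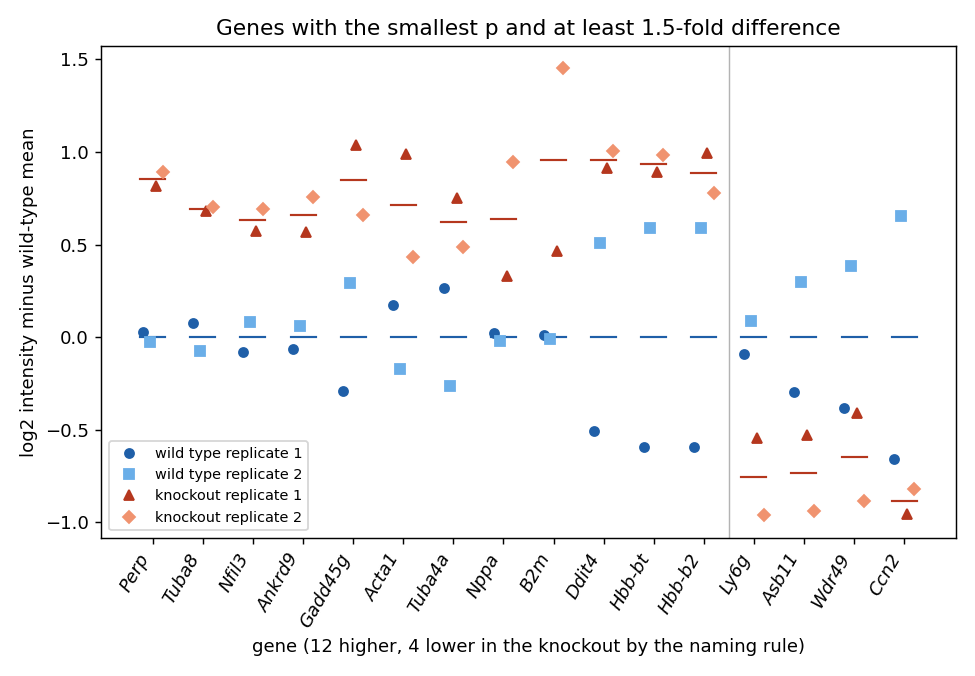
Normalized log2 intensity of the 16 named genes on each array, minus the wild-type mean of the gene (points, 1 per array; horizontal lines, group means; n = 2 arrays per group). The knockout mean of Perp lies 0.85 above the wild-type mean with little spread, whereas Ddit4, Hbb-bt and Hbb-b2 have 1 low wild-type array and Ccn2 has 1 high wild-type array.

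Genes of fatty acid uptake and oxidation lay lower in the knockout as a group. Of 45 measured, 33 were lower and 12 higher, with 9 lower and 3 higher at an unadjusted p under 0.05 and none past the test over all genes or adjusted over the list alone. The median log2 fold change was -0.054, or 3.85% lower, with a camera adjusted p of 0.00395, and adjusted p = 0.88 with an estimated correlation. Acot1, a thioesterase of long-chain acyl-CoA, had a log2 fold change of -0.42 ± 0.06, and Slc25a20, the carnitine-acylcarnitine carrier of mitochondria, one of -0.39 ± 0.07. Etfa, a subunit of the electron transfer flavoprotein, was at 12.42 ± 0.18 and 11.97 ± 0.01, and Eci1, an enoyl-CoA isomerase, at 11.70 ± 0.05 and 11.48 ± 0.02. Fabp4, 1 of the 3 higher at an unadjusted p under 0.05, had a log2 fold change of 0.22 ± 0.07. The call held without any 1 of the arrays, with an adjusted p of 0.00297 to 0.0342, passed narrowly with an offset of 0, at 0.0489, and ended in the authors' table, at 0.442 with a median of -0.040, and after local background subtraction, at 0.928, where the median was 0.0024 and no longer lower. Over all alternatives it ranged from 7.35e-06 to 0.928.

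Other metabolic lists were not called. Of 75 oxidative phosphorylation subunits 41 were higher and 34 lower, with an adjusted p of 0.804. Their median of 0.022 was -0.021 without the second wild-type array, -0.014 without the first knockout array and -0.016 with median scaling, so that no direction held. Ndufa1 of complex I was -0.18 ± 0.04, and Atp5d of the ATP synthase, Uqcrc1 of complex III and Cox7b of complex IV were 0.18 ± 0.05, 0.21 ± 0.08 and 0.12 ± 0.04. Of 35 genes of glucose uptake and glycolysis 22 were higher and 13 lower, with an adjusted p of 0.107. Pgam1, phosphoglycerate mutase, was at 9.96 ± 0.17 and 10.35 ± 0.07, Igf1r and Ugp2 were 0.26 ± 0.06 and 0.17 ± 0.05, and Ldha, lactate dehydrogenase A, was -0.25 ± 0.06. In the 37 genes of the oxidative stress response and NADPH oxidase, Gstm2, a glutathione transferase, passed adjusted over the list alone at 0.0287, with 9.18 ± 0.03 in wild type and 8.84 ± 0.04 in the knockout. Over all genes Gstm2 had a limma adjusted p of 0.727. Gsta4, Rac1 and catalase (Cat) were -0.21 ± 0.07, -0.31 ± 0.10 and -0.19 ± 0.08, and the list had a camera adjusted p of 0.179, which was under 0.05 after scaling to the median (0.0222) or the 75th percentile (0.00435) and 0.88 with an estimated correlation. In the 21 genes of sulfur amino acid and persulfide metabolism, with an adjusted p of 0.902, Slc3a2 and Slc7a5, the 2 chains of an amino acid transporter, were 0.19 ± 0.04 and -0.29 ± 0.07, Mtr was 0.22 ± 0.08 and Bhmt -0.09 ± 0.04.

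Cytosolic ribosomal protein genes lay higher, with 36 of 49 above wild type, 9 of them and 0 of the lower genes at an unadjusted p under 0.05. The median was 0.049, or 3.45% higher, with a camera adjusted p of 0.00395, and adjusted p = 0.88 with an estimated correlation. Rps27 was at 12.25 ± 0.01 and 12.50 ± 0.00, Rpl15 at 10.97 ± 0.07 and 11.24 ± 0.05, and Rps9 and Rpl3 were 0.18 ± 0.04 and 0.17 ± 0.05. The direction turned after local background subtraction, with a median of -0.027, and the call ended without the first knockout array, at 0.0593 with a median of 0.034, with 75th percentile scaling, at 0.111 with one of 0.068, and with an offset of 0, at 0.123 with one of 0.069, within a range of 0.00106 to 0.887 over the alternatives. Cell cycle genes were higher in 22 of 29, with a median of 0.049 and a camera adjusted p of 0.0219, and adjusted p = 0.88 with an estimated correlation. Top2a, DNA topoisomerase II, was 0.15 ± 0.04 and above background on 1 of 2 wild-type arrays, Ccnd3, cyclin D3, was 0.14 ± 0.04, the replication factor Mcm5 was 0.12 ± 0.04, and Ube2c, a ubiquitin-conjugating enzyme of mitosis, was -0.16 ± 0.05. That call ended without either wild-type array (0.0740 and 0.0966), without the first knockout array (0.302), with 75th percentile scaling (0.111), after local background subtraction (0.887) and among genes above background on all arrays (0.216), with medians of 0.041 to 0.099 in these fits, within a range of 2.29e-05 to 0.887 over the alternatives.

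Immediate early genes, transcribed within minutes of a stimulus or of handling, lay lower in 21 of 28. The median was -0.065, or 4.59% lower, with a camera adjusted p of 0.00802, and adjusted p = 0.88 with an estimated correlation. Btg2, an antiproliferative factor, passed adjusted over the list alone at 0.0413 and was at 7.08 ± 0.08 in wild type and 6.68 ± 0.05 in the knockout. Over all genes Btg2 had a limma adjusted p of 0.727. Jun was at 8.14 ± 0.16 and 7.80 ± 0.05, and Socs3 and Nr4a1 were -0.16 ± 0.06 and -0.18 ± 0.07. The call ended without the second wild-type array, at 0.588, without the second knockout array, at 0.0925, and after local background subtraction, at 0.928, with medians of -0.034, -0.032 and -0.013, within a range of 6.71e-05 to 0.928 over the alternatives. Glucocorticoid targets were higher in 11 of 14, with a median of 0.11, a camera adjusted p of 0.0219, and adjusted p = 0.88 with an estimated correlation. Ddit4 and Mt1, a metallothionein at 11.28 ± 0.67 and 12.04 ± 0.31, were low on the first wild-type array, while Klf9 and Errfi1 were 0.08 ± 0.04 and 0.13 ± 0.07. Without that array the adjusted p was 0.911 and camera's direction turned, with a median of 0.042; without the second knockout array it was 0.523 with a median of 0.049. With 75th percentile scaling it was 0.221, with median scaling 0.0888 and after local background subtraction 0.778, with medians of 0.12, 0.090 and 0.14, and over all alternatives it ranged from 2.62e-11 to 0.911.

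**Figure D2:**
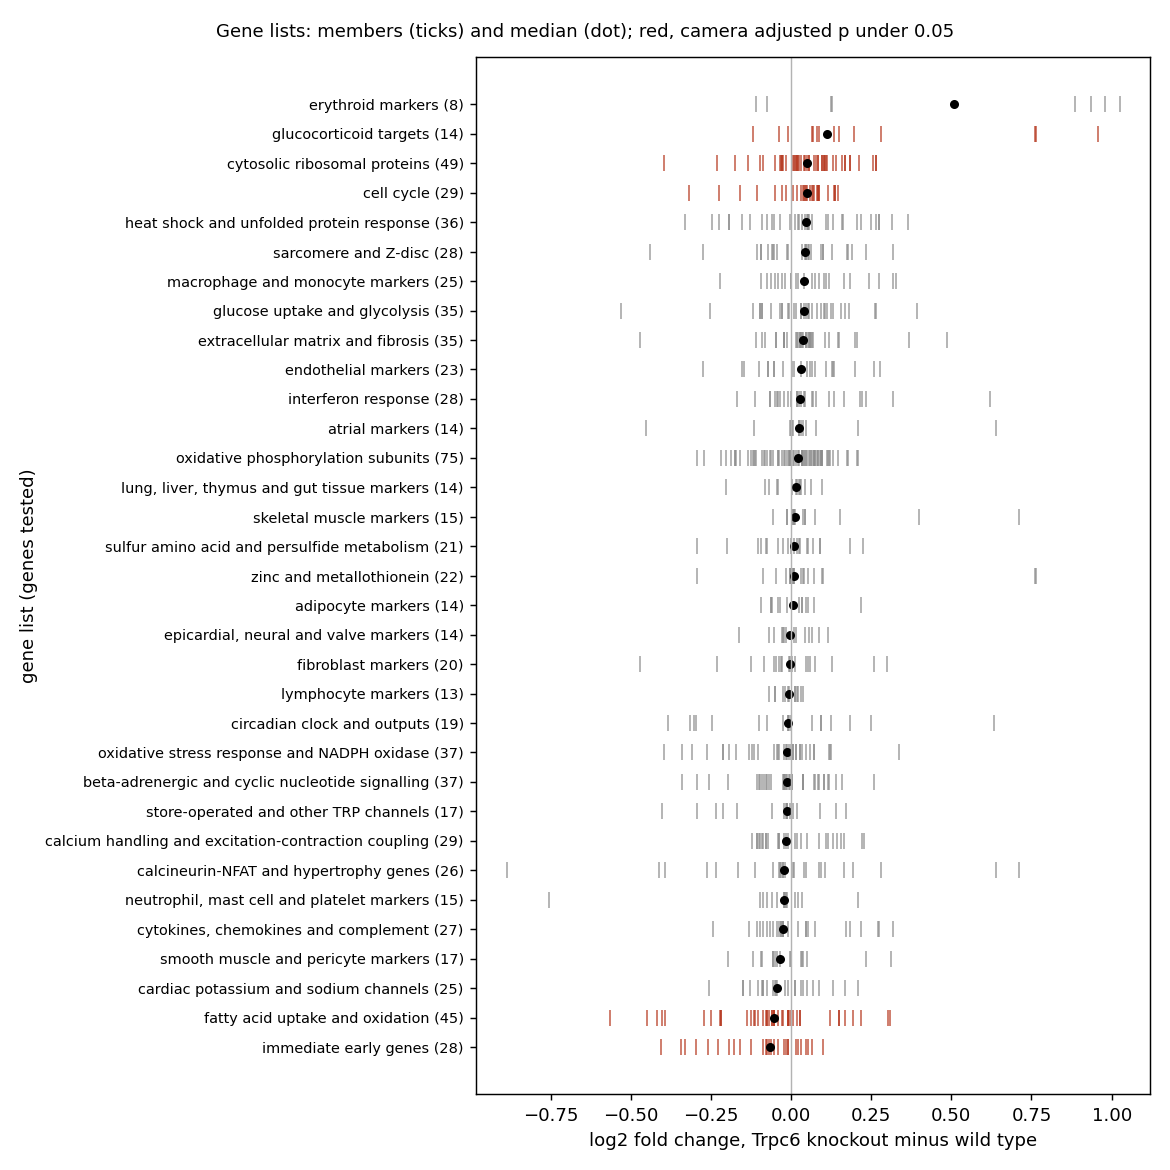
Log2 fold change, knockout minus wild type, of the members of the 33 gene lists tested (ticks, 1 per gene), with the median of each list (dots) and the number of genes tested in brackets. The 5 lists in red had a camera adjusted p under 0.05 with the preset correlation, and their medians lie between -0.065 and 0.11.

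Genes around the pathway that TRPC6 is known to feed, calcineurin and NFAT, went both ways. Of 26 calcineurin-NFAT and hypertrophy genes 12 were higher and 14 lower, with 4 in each direction at an unadjusted p under 0.05, with a camera adjusted p of 0.804. The mixed test of fry, which asks whether genes of a list differ in either direction, gave an adjusted p of 0.0277. That value is for the main fit with all arrays and is not given for the alternatives. Besides Acta1, Nppa and Ccn2, this list held Mef2a, a cardiac transcription factor, at 8.65 ± 0.07 and 8.38 ± 0.04, Hdac5, a repressor of MEF2, at 9.32 ± 0.06 and 8.91 ± 0.19, Edn1, endothelin 1, at 6.49 ± 0.03 and 6.33 ± 0.01, and Xirp1, an actin-binding protein of intercalated discs, at 6.89 ± 0.06 and 7.05 ± 0.02. None passed adjusted over the list alone.

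Signalling and channel lists were not called. In the 37 genes of beta-adrenergic and cyclic nucleotide signalling, with an adjusted p of 0.549, Pde4b, a cAMP phosphodiesterase, was -0.34 ± 0.05, the receptor kinase Grk5 was -0.26 ± 0.05, and the G protein regulators Rgs2 and Rgs4 were 0.26 ± 0.06 and -0.29 ± 0.10. Of 17 store-operated and other TRP channel genes 12 were lower, with an adjusted p of 0.485. Saraf, an inhibitor of store-operated entry, was at 10.45 ± 0.16 and 10.05 ± 0.09, Trpv2 was -0.24 ± 0.06, and Mcoln1 and the calcium sensor Stim1 were 0.17 ± 0.05 and 0.14 ± 0.05. In the 29 genes of calcium handling, with an adjusted p of 0.922, Calm3, Fkbp1a and Trdn were 0.22 ± 0.06, 0.13 ± 0.04 and 0.16 ± 0.06, and phospholamban (Pln) was -0.10 ± 0.05. In the 25 potassium and sodium channel genes, with an adjusted p of 0.420, Kcnd2 and the connexin gene Gjc1 were both -0.15, with standard errors of 0.04 and 0.05, and Kcnj12 and Fxyd1 were 0.17 ± 0.07 and 0.13 ± 0.06. In the 22 zinc and metallothionein genes, with an adjusted p of 0.549, the zinc transporters Slc30a9, Slc39a1 and Slc39a8 were -0.29 ± 0.11, -0.09 ± 0.04 and 0.07 ± 0.04, the last above background on 1 of 2 wild-type arrays.

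Structural genes were not called either. In the 28 sarcomere and Z-disc genes, 16 of them higher and with an adjusted p of 0.549, Myl3, a ventricular light chain, was 0.23 ± 0.08, and Ldb3, Flnc and Myoz2 were -0.44 ± 0.18, 0.32 ± 0.14 and 0.19 ± 0.09. In the 35 extracellular matrix genes, 25 of them higher and with an adjusted p of 0.228, fibronectin (Fn1) was at 7.06 ± 0.03 and 7.43 ± 0.11 and decorin (Dcn) at 11.50 ± 0.00 and 11.03 ± 0.26, while Col3a1 and Col5a2 were 0.49 ± 0.30 and 0.15 ± 0.09, and 0.03 and 0.05 without the second wild-type array. In the 36 heat shock and unfolded protein genes, 23 of them higher and with an adjusted p of 0.179, the small heat shock protein Hspb1 was 0.22 ± 0.04, its partner Bag3 0.25 ± 0.05, the mitochondrial chaperonin Hspe1 0.21 ± 0.05, and the endoplasmic reticulum chaperone Hspa5 -0.19 ± 0.04. The extracellular matrix list passed without the first wild-type array (0.0178), and the heat shock list passed without the second wild-type array or without the first knockout array (0.0284 at the lowest). Both had an adjusted p of 0.88 with an estimated correlation.

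Circadian clock genes were not called as a group, with 7 of 19 higher, 12 lower and a camera adjusted p of 0.804. In this list 3 genes passed adjusted over the list alone, with a smallest value of 0.0124, while over all genes each had a limma adjusted p of 0.727. They were Nfil3, described above, and the nuclear receptor repressors Nr1d2, at 9.21 ± 0.02 in wild type and 8.96 ± 0.03 in the knockout, and Nr1d1, at 6.35 ± 0.12 and 5.97 ± 0.07. Tef was 0.13 ± 0.04. Sampling times were not given in the sources used here.

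No immune list was called. In the 28 interferon response genes, with an adjusted p of 0.549, Ddx58 and Oas1a were -0.17 ± 0.05 and -0.11 ± 0.04, and Ifit3 and Psmb8 were 0.22 ± 0.10 and 0.32 ± 0.15. The list passed without the first knockout array, at 1.58e-04, and had an adjusted p of 0.939 with an estimated correlation. In the 27 cytokine, chemokine and complement genes, with an adjusted p of 0.939, Ccl9 was 0.27 ± 0.07 and Ccl6 0.22 ± 0.11, and C1qa and C1qb were 0.32 ± 0.09 and 0.27 ± 0.10. These C1q genes also led the 25 macrophage and monocyte markers, 17 of them higher, with an adjusted p of 0.276, followed by Itgam (0.11 ± 0.04, above background on 1 of 2 wild-type arrays) and Ly6c2 (0.33 ± 0.17). The 13 lymphocyte markers had an adjusted p of 0.804, and Cd4, Cd3d, Cd79b and Cd247 were between -0.07 and 0.04. The 15 neutrophil, mast cell and platelet markers had an adjusted p of 0.173. Apart from Ly6g they included Ppbp, Mcpt4 and Pf4, at -0.10 ± 0.05, -0.09 ± 0.05 and 0.21 ± 0.14, and the list passed in the authors' table (0.0105) and with an offset of 0 (0.0311), and had an adjusted p of 0.88 with an estimated correlation.

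Markers of other cell types and tissues were measured for the makeup of the samples, and none of these lists was called. The 8 erythroid markers had a median of 0.51 and an adjusted p of 0.105, and without the first wild-type array a median of 0.17 and an adjusted p of 0.0740. Hba-a2 was at 9.45 ± 1.02 and 10.47 ± 0.03, with the first wild-type array low, and the heme enzyme gene Alas2 was 0.13 ± 0.04. Without the second wild-type array the erythroid list had a median of 0.82 and an adjusted p of 1.71e-08 and Hba-a2 passed over all genes at 0.0487; the list also passed with offsets of 16 (0.0194) and 0 (0.0311), without the filter, with the replicate number as a term (0.0400) and in the authors' table (8.06e-04). With an estimated correlation its adjusted p was 0.88. Endothelial markers (23 genes, adjusted p 0.804) included Egfl7 at -0.27 ± 0.05, Flt1 at 0.20 ± 0.10, Eng at 0.13 ± 0.07 and Ly6c1 at 0.28 ± 0.14. Fibroblast markers (20 genes, 0.902) included Lamc1 at 0.30 ± 0.06, Mgp at 0.26 ± 0.07 and Ddr2 at -0.08 ± 0.04, besides Dcn. Smooth muscle and pericyte markers (17 genes, 0.804) included Acta2 at 0.31 ± 0.17, Cnn1 at -0.12 ± 0.07, Rgs5 at -0.20 ± 0.15 and Smtn at 0.23 ± 0.18.

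Atrial markers (14 genes, adjusted p 0.549) apart from Nppa included Pam at 0.21 ± 0.11, Bmp10 at -0.12 ± 0.06 and Tbx5 at 0.08 ± 0.06. In the 15 skeletal muscle markers, with an adjusted p of 0.179, Tnnt1, slow skeletal troponin T, was at 7.19 ± 0.13 and 7.58 ± 0.04, Ckm was 0.15 ± 0.08 and Tnni2 -0.06 ± 0.04, and the list passed without the first wild-type array (0.0163), with an adjusted p of 0.88 at an estimated correlation. Adipocyte markers (14 genes, 0.979) included Fabp4 at 0.22 ± 0.07, and Pck1, Retn and Ucp1 were between -0.06 and 0.04. Epicardial, neural and valve markers (14 genes, 0.804) included Upk3b at 0.12 ± 0.04, Chad at -0.16 ± 0.06, Msln at 0.09 ± 0.05 and Sox10 at 0.07 ± 0.04. Markers of lung, liver, thymus and gut (14 genes, 0.868) included Serpina1a at -0.20 ± 0.10, while Scgb1a1, Fgb and Alb were between -0.08 and -0.04. Of the sex chromosome genes 3 were kept, and Xist, Kdm5d and Eif2s3y had log2 fold changes of 0.03 ± 0.04, -0.02 ± 0.06 and -0.01 ± 0.07.

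Genes near Trpc6 on chromosome 9 were compared with the rest of that chromosome, since a knockout can carry flanking sequence of another strain. The median log2 fold change of 60 genes within 10 Mb differed by -0.0032 from that of 861 genes elsewhere on the chromosome, with a permutation p of 0.801 by circular shifts. Such a median would not move if some neighbours were higher and others lower. Within the window 0 genes passed with limma and 2, Alkbh8 at 0.13 ± 0.04 and Smco4 at -0.12 ± 0.04, had an unadjusted p under 0.05. By the same circular shifts, the one-sided p for a count at least this high was 0.867. Both genes were named after their values were seen.

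The arrays were compared in pairs. Across genes, which are not independent replicates, Pearson's r was 0.994 between the wild-type arrays and 0.997 between the knockout arrays, and 0.993 to 0.997 between groups. The SD of log2 differences was 0.14 within wild type, 0.10 within the knockout and 0.10, 0.13, 0.14 and 0.15 for the 4 pairs of arrays between groups, lowest for the first arrays of each group and highest for the second.

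**Figure D3:**
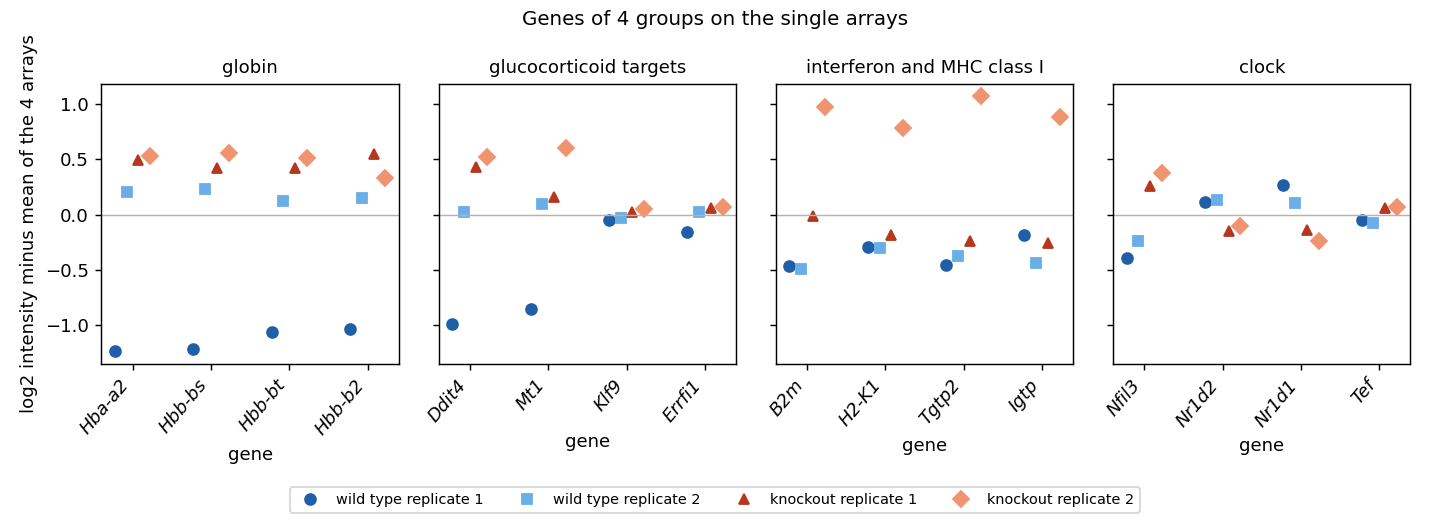
Normalized log2 intensity minus the mean of the 4 arrays, for 4 genes each of globin, glucocorticoid targets, interferon and MHC class I, and the clock (points, 1 per array). Globin genes, Ddit4 and Mt1 are low on the first wild-type array, the interferon and MHC class I genes shown, which besides B2m were chosen after their values were seen, are high on the second knockout array, and for the clock genes shown, the leading members of their list by p, the groups do not overlap.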

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

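The alternatives were fixed before the data were examined, except normexp after local background subtraction and normexp with an offset of 0, which were chosen after seeing the data. The count of genes past the threshold with limma was 0 under each planned and added alternative, except that leaving out arrays gave a range of 0 to 1. In place of 5 lists, 75th percentile scaling called 3, camera with an estimated correlation 0, fry's test of a shared direction 0 and normexp after local background subtraction 0, and leaving out arrays gave a range of 3 to 5. The other alternatives called 4 to 6. Of the lists that passed only under some alternatives, the highest camera adjusted p over the alternatives lay between 0.880 and 0.974. The ribosomal list turned to -0.027 and the fatty acid list went to 0.0024 after local background subtraction, and glucocorticoid targets turned in camera's direction without the first wild-type array, with medians of 0.042 to 0.43 over the fits without single arrays. The difference of genes near Trpc6 turned to 0.0025 with 75th percentile or median scaling, to 0.0022 after local background subtraction and to 0.0085 in a 5 Mb window, and ranged from -0.015 to 0.0085 without single arrays. Trpc6 was listed on 1 array in the authors' table against 0 above background. The lowest correlation between arrays, 0.993, moved to 0.985 in the authors' table, 0.988 with an offset of 0 and 0.910 after local background subtraction, and lay between 0.993 and 0.995 without single arrays. The cause was not tested for any of these. Leaving out an array also lowered the number of samples, and the lone sample left was assumed to vary like the other group.

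The signs of the 16 leading genes held under every alternative run except local background subtraction, which turned 3. With that alternative 44 of the 128 genes named from lists changed sign, 5 did without the second wild-type array, 3 without the first knockout array, 3 with 75th percentile scaling, 2 in the authors' table and 1 each without the first wild-type or the second knockout array. Of 135 genes named from lists, those also among the leading genes included, 39 kept less than 50% of their fold change in the fit without 1 array that weakened them most. Without the second knockout array 250 genes were higher and 194 lower at an unadjusted p under 0.05, and without the first wild-type array 1143 and 1201. With only 3 ways to split 4 arrays into pairs, no share under 0.05 can arise. The real split gave 1076 genes at an unadjusted p under 0.05 and 5 lists. Setting the first arrays of both groups against the second gave 805 genes and 3 lists, and the remaining split gave 337 genes and 4 lists. Glucocorticoid targets and immediate early genes, called in the real split, were each also called in 1 of the others.

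The replicate numbers were not treated as pairs, a choice fixed beforehand because the titles do not say that they pair. In the data, deviations of same-numbered arrays correlated at 0.097 across genes, and there were 2 pairs. With the replicate number as a block, 0 genes and 6 lists were called, the erythroid list at 0.0400. Slide as a block was not run, since the files give no slide that holds several arrays. Trpc6, below background, gave no value under the remaining alternatives. Low signal limits dim genes, since the median probe read 95.5 to 106 units and the median blank spot 78.5 to 87.6 units.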

Other observations

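The tests on sarcomere against fatty acid genes, on normexp with an offset of 0 and on clock groups were chosen only after the results were seen, and the planned fits without single arrays were read for the fatty acid pattern only then.

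Some interferon-inducible and MHC class I genes were high on the second knockout array, and those named here besides B2m were chosen after their values were seen. Tgtp2, an interferon-inducible GTPase, was at 6.18 and 6.26 in wild type and at 6.40 and 7.71 in the knockout, and Igtp, another such GTPase, at 7.49, 7.24, 7.42 and 8.56 in the same order. H2-K1, a heavy chain of MHC class I, was at 8.46, 8.45, 8.57 and 9.54, while H2-D1 was at 5.94, 5.78, 5.86 and 5.88. The H2-D1 probe was dim, where the offset shrinks differences, so its values do not show that it was unchanged. Of all 28 interferon genes 17 were highest and 2, Ddx58 and Oas1a, lowest on the second knockout array, which lay 0.10 above the mean of the others as a median. Mt2 followed Mt1, at 7.77 and 8.77 in wild type and 8.69 and 9.37 in the knockout.

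The globin genes were low on the first wild-type array. Their 4 probes lay 1.51 ± 0.14 lower there than on the other 3 arrays on the log2 scale (mean ± SD over probes), or 2.86-fold, and the knockout mean lay 0.30 ± 0.04 above the second wild-type array. Probes of these paralogs are open to cross-hybridisation and are not independent, and no explanation was tested.

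The fatty acid list lay lower in the knockout by camera at a preset correlation, and was not called with an estimated one (adjusted p = 0.88) or with fry for a shared direction (0.615). With normexp at an offset of 0 the list's median was -0.076, with a bootstrap interval of -0.11 to -0.028, and its adjusted p of 0.0489 passed only narrowly, so an offset of 50 was not needed for the shift. If 1 array set the shift, leaving it out would end the call, and the highest adjusted p of the 4 such fits, at the preset correlation, was 0.0342. A lower share of cardiomyocytes would lower sarcomere genes as well, and their median of 0.045 lay above that of the fatty acid genes at a permutation p of 0.00196, by 0.0042 to 0.14 as a bootstrap interval with all arrays and by an interval above 0 without either wild-type or the first knockout array, yet this share stays open, since without the second knockout array the interval was -0.048 to 0.14, 16 of 28 sarcomere genes were higher, and both tests take genes as independent. Genotype, differences between the animals such as feeding, and the handling of background may contribute and stay open, as the median went from -0.054 (-0.077 to -0.010) to 0.0024 (-0.098 to 0.13) after local background subtraction, where the SD over genes was 0.91 in place of 0.19.

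Some clock genes were higher and others lower in the knockout, without a settled pattern by phase. Of genes that peak together with Nr1d1, 8 were kept, with a mean log2 fold change of -0.09 ± 0.20 (SD over genes). Nr1d1 (-0.38), Dbp (-0.30), Nr1d2 (-0.25) and Ciart (-0.10) were lower, Hlf and Per3 near 0, and Tef (0.13) and Usp2 (0.18) higher. The 4 of the opposite phase had a mean of 0.20 ± 0.32, carried by Nfil3 (0.63) and Cry1 (0.25), with Arntl at -0.01 and Clock at -0.07. Those besides Nr1d1, Nr1d2, Tef and Nfil3 were named after their values were seen. The difference of 0.29, with a bootstrap interval of 0.010 to 0.61, had an exact permutation p of 0.0808 over 495 assignments of genes. A shift of clock phase between the groups, from time of sampling or from genotype, may be involved, but the test did not pass and the genes are few, so this stays open.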
